A study of Homo sapiens with 6 samples.

How the data were processed

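SMAD2 ChIP-seq had been carried out in Hs578T cells with an antibody against SMAD2, in 2 libraries after activin A and 2 after palbociclib with activin A. There was also 1 input library, which is sonicated genomic DNA without immunoprecipitation, per treatment. The peak lists of the 4 ChIP libraries were analysed, and the 2 input libraries were not analysed here as data of their own. Per the labels' protocols, libraries were built with a fragment library kit for Ion sequencers and amplified by PCR. Per the submitters' processing notes, Bowtie 1.1.0, Picard and MACS2 2.0.9 were used with the human genome build hg19; their order and settings are not given in the sources used here. Bowtie is a short-read aligner, Picard a toolkit that includes removal of PCR duplicates, and MACS2 a peak caller. Per the labels, each ChIP library was called against the input of its own treatment. The input is therefore confounded with the treatment, because both replicates of a treatment share it. Replicates were not pooled.

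The deposited lists hold 1-base summit positions on hg19, and the authors' score of each peak is on a −log10 scale. The lowest scores of the 4 lists lie between 1.31 and 1.4, just above 1.30, which is −log10 of 0.05. The score was read as −log10 of a q-value (a p-value adjusted for many tests) from this minimum; whether it is a p or a q is not stated elsewhere. Such a score grows with sequencing depth as well as with enrichment. It was used only to rank or filter summits within a list, or to rank the same sites within each list. The number of reads per library is not given in the sources used here, so the depth is unknown. The numbers of summits, from 7241 to 27290, are the only measure of it, and they also move with the efficiency of the immunoprecipitation. Peak width, height and fold enrichment were not used here.

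All 4 lists were restricted to chromosomes 1 to 22, X and Y, which removed 0 summits. Summits of all lists on a chromosome were sorted, and those within 250 bp of the next formed 1 site. A site was present in a library with at least 1 summit there; its score was the best summit's. Coordinates are 1-based on hg19, from the first to the last summit of a site. Overlap between libraries was the Jaccard index. Chance overlap came from 100 sets of lists in which 3 of the 4 lists were shifted by random distances along each chromosome, wrapping at the last summit. Shares carry Wilson 95% intervals, which cover counting error only. Equal-length lists kept the 7241 best scores of each library, with ties ordered by position. The group difference in summit number was tested by an exact permutation test on log2 numbers, for which 2 against 2 libraries cannot go below p = 0.333. Site counts were not tested and were set beside those of the other ways to pair the 4 libraries. For ranks and positions, the variation between 4 libraries was divided into the contrasts of the 3 ways to split them 2 against 2: by treatment, by replicate number, or neither. With independent libraries each takes 33.3% of the mean square on average, whatever the noise of each library. The count of sites at which the pairs of a split do not overlap depends on that noise, so its value with no effect was simulated, with normal errors whose SD came from the replicates of each treatment (11.9 percentile points for activin and 8.11 for palbociclib). Correlations across chromosomes or windows carry permutation p-values from 100000 permutations.

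The site functions were tested on simulated lists. All 2000 sites planted in all 4 libraries, 200 planted as palbociclib-only and 100 planted as activin-only were recovered. Planted sites lay over 2000 bp apart, so this recovery checks the code only. It does not cover real sites with a summit of the other treatment close by. With no planted effect, treatment took 32.5% of the rank variation over 2000 simulated sites, or 33.0% with activin replicate 2 made noisier, and with scores changed at a subset of sites it took 83.9%. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

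The named sites followed a rule fixed before the data were examined. They are the 10 sites with the best mean rank within the lists among sites in all 4 libraries, among palbociclib-only sites and among activin-only sites. Sites named for the largest change of percentile between treatments were chosen after their values were seen. Comparisons by site rank, by window and by leading site were also added at that point. The rule also covered genes next to the sites, and lists of genes and motifs had been fixed. A genome and a gene annotation of hg19 were not used here, and coordinates were not converted between builds. So the shares of sites in promoters, the gene list results and the motif results were not analysed here, and sites are given by position. The gene table used, of assembly GRCh38.p14, served only to count protein-coding genes per chromosome. Alternatives covered joining distances of 100, 500 and 1000 bp, score thresholds, equal list lengths, a wider reach of absence (2000 bp), the replicate number as a block and leaving out each library.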

Results

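Genome-wide binding of SMAD2 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in Hs578T cells. Hs578T is an established human cell line of triple-negative breast cancer, the subtype that lacks the oestrogen and progesterone receptors and HER2 amplification. SMAD2 is a transcription factor of the activin and TGF-β pathway that is phosphorylated by the activated receptor and then gathers in the nucleus. All cells received activin A at 50 ng/ml for 1.5 h. One group received activin A alone (here the activin group, 2 libraries). The other group also received 1 µM palbociclib for 24 h (here the palbociclib group, 2 libraries). Palbociclib is an inhibitor of the cyclin D-dependent kinases CDK4 and CDK6. The question the design addresses is how SMAD2 binding after activin differs when these kinases are inhibited. There was no ChIP library without activin, so activin-induced binding could not be separated from binding present before stimulation. Replicates were labelled as separate samples, with no statement on separate cultures, so the spread between them may be technical.

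Each list gave the summit, the single base of highest signal, of every SMAD2 peak. The activin libraries held 25553 summits in replicate 1 and 7241 in replicate 2, a mean of 16397 ± 12948 (SD, n = 2). The palbociclib libraries held 27290 summits in replicate 1 and 19226 in replicate 2, a mean of 23258 ± 5702 (SD, n = 2). The ratio of the geometric means was 1.68 in favour of the palbociclib group, or 0.75 on the log2 scale. The exact permutation test of 2 against 2 libraries gave p = 0.667 (two-sided), and the smallest p this design allows is 0.333. Within replicate 1 the palbociclib library had 1.07 times as many summits as the activin library, and within replicate 2 it had 2.66 times as many. The activin replicates differed from each other by 3.53 times, which was more than the difference between the groups. Without activin replicate 2 the log2 ratio was -0.16, so 1 library set the direction of the difference; without activin replicate 1 it was 1.66 and without palbociclib replicate 1 it was 0.50. Among summits with a score of at least 20, a threshold added after the data were seen, the log2 ratio was 1.71. Such summits numbered 10639 and 888 in activin replicates 1 and 2, and 12119 and 8374 in palbociclib replicates 1 and 2. The size of this ratio thus also rested on activin replicate 2.

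Summits of the 4 lists that lay within 250 bp of the next were joined into 36648 binding sites. Of these, 5829 sites were found in all 4 libraries, which is 15.9% of all sites (Wilson 95% interval 15.5 to 16.3). In 100 sets of lists shifted at random along the chromosomes, no site was shared by all 4. These shifts ignore where summits tend to gather along a chromosome, so they are a lenient reference. Another 8594 sites were found in 3 libraries, 7666 in 2 and 14559 in 1. The short list limited the first number: without activin replicate 2, 14053 sites were shared by the other 3 libraries. Of the 7220 sites of activin replicate 2, 90.2% were also in another library (89.5 to 90.8). The corresponding shares were 80.6% for activin replicate 1, 74.5% for palbociclib replicate 1 and 89.6% for palbociclib replicate 2. Strong sites recurred more than weak ones. Among the best-scored 25% of sites, 97.8% to 99.4% of a library's sites were found in another library. Among the weakest 25% this share was 50.2% in activin replicate 1, 32.3% in palbociclib replicate 1, 80.8% in activin replicate 2 and 72.7% in palbociclib replicate 2.

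**Figure D1:**
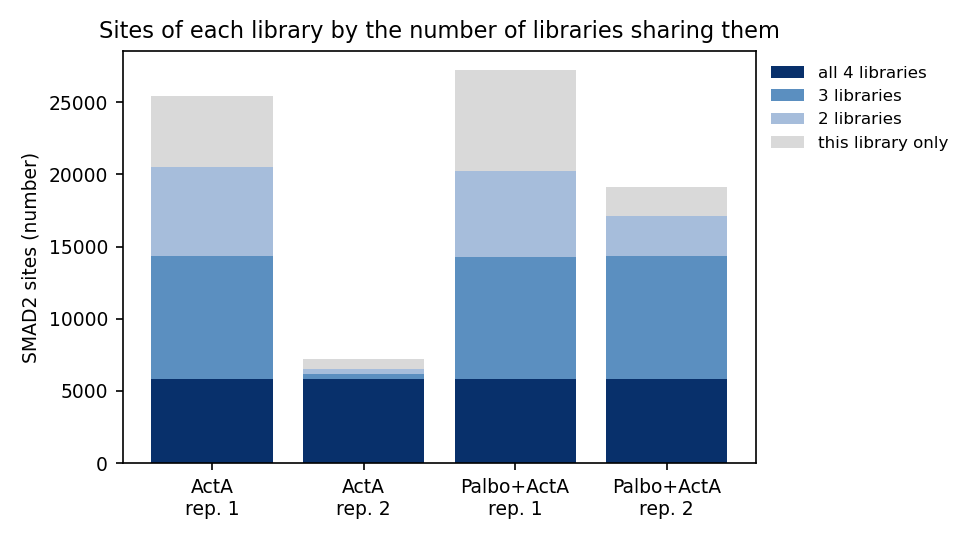
Number of SMAD2 binding sites in each of the 4 libraries (vertical axis, from 0), with each bar divided by how many libraries share the sites. The 5829 sites common to all 4 libraries form the base of every bar and most of the bar of activin replicate 2, which has 7220 sites.

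The 10 strongest sites common to both treatments ranked between 1 and 27 in every library. The best mean rank over the 4 lists was 1.75, at a site on chromosome 1 from 45187391 to 45187446 (hg19). It ranked first in activin replicate 1 and in both palbociclib libraries, and at rank 4 in activin replicate 2. The next site lay on chromosome 15 from 65597286 to 65597363, with a mean rank of 3.75 ± 1.77 in the activin group and 6.0 ± 4.24 in the palbociclib group (SD, n = 2 each). It was followed by sites on chromosome 1 from 147806682 to 147806738 (mean rank 6.25), on chromosome 2 from 122288636 to 122288666 (6.5) and on chromosome 17 from 8076677 to 8076818 (7.0). A site on chromosome 1 from 28975109 to 28975371 had a mean rank of 3.5 ± 3.54 in the activin group and 11.5 ± 0.71 in the palbociclib group. The ranks of the remaining 4 sites among the best 10 averaged 10.2 to 14.5. These lay on chromosome 15 from 65588410 to 65588626, on chromosome 1 from 146556000 to 146556116, on chromosome 17 from 56756845 to 56757033 and on chromosome 1 from 210547319 to 210547407. The 10 sites lay on 4 chromosomes, and 5 of them were on chromosome 1. Their position relative to genes was not analysed here. Signal at these sites from any immunoprecipitation was not separated from SMAD2 binding, because no control antibody library was analysed here.

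**Figure D2:**
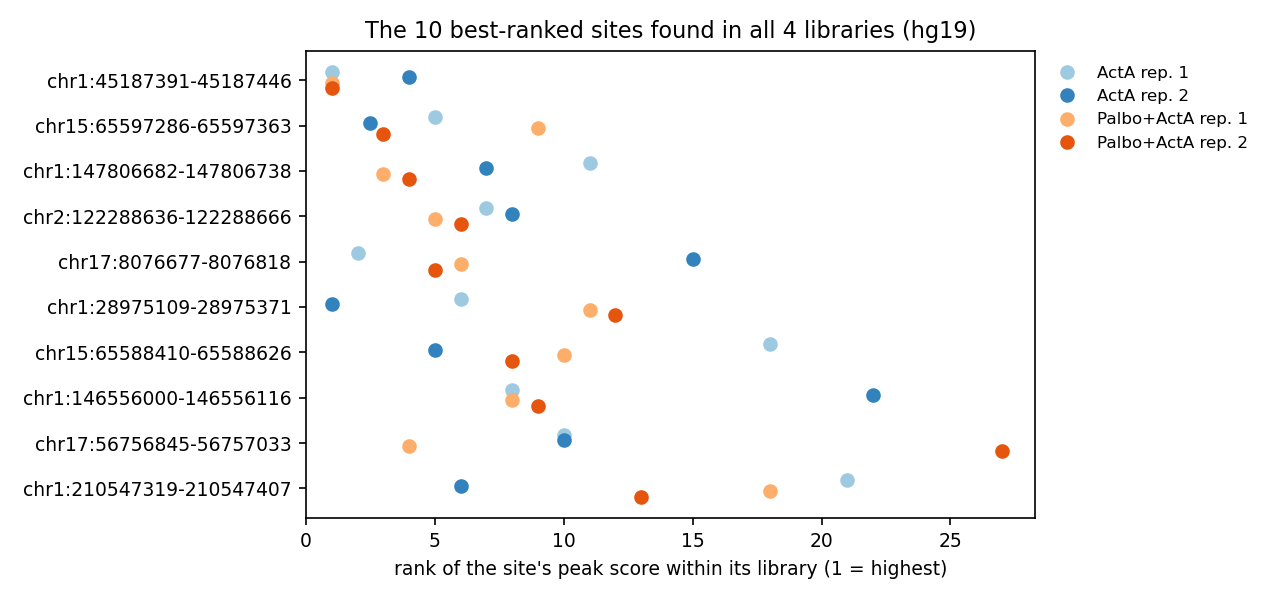
Rank of the peak score within each library (horizontal axis, 1 is the highest score) for the 10 sites with the best mean rank among those found in all 4 libraries. Each point is 1 library, coloured by group and replicate; the first site ranks 1 in 3 libraries and 4 in activin replicate 2.

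Pairs of libraries were compared to see whether replicates of a treatment shared more sites than libraries of different treatments. By the share of sites in both among sites in either (the Jaccard index), the palbociclib replicates shared 50.0% and the activin replicates 23.6%. Between treatments the index was 55.7% for the replicate 1 libraries and 30.9% for the replicate 2 libraries. It was 54.0% for activin replicate 1 with palbociclib replicate 2, and 21.4% for activin replicate 2 with palbociclib replicate 1. The mean within treatments was 36.8% and the mean between treatments 40.5%. Unequal list lengths cap the index, so the full lists cannot show whether overlap parted the libraries by treatment. In lists of equal length these means were 70.1% and 67.6%. There the palbociclib replicates shared 78.0% and the activin replicates 62.1%. Activin replicate 1 shared 76.2% and 73.2% with palbociclib replicates 1 and 2, and activin replicate 2 shared 59.5% and 61.5%. Every value of the full lists was far above the random shifts, whose highest index over the 6 pairs was 0.434%. The shifts do not cover overlap that comes from a shared preference for certain regions. The ranks of the peak scores parted the libraries by treatment in the mean. Across the 5829 common sites, Spearman's rho was 0.921 between the palbociclib replicates and 0.831 between the activin replicates. Between treatments rho was 0.832 for the replicate 1 libraries, 0.791 for activin replicate 1 with palbociclib replicate 2, 0.726 for the replicate 2 libraries and 0.706 for activin replicate 2 with palbociclib replicate 1. The mean within treatments was 0.876 and the mean between treatments 0.764, a difference of 0.112. One between-treatment pair, at 0.832, thus lay just above the activin replicates at 0.831. These correlations run across sites, which are not independent replicates.

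Sites found in both palbociclib libraries and in neither activin library numbered 1303, and sites found in both activin libraries and in neither palbociclib library numbered 126. These counts were set beside the same counts for every other pair of libraries, since 6 ordered pairs cannot give a test below 0.05. The 1303 palbociclib-only sites ranked 3 among the 6 counts and the 126 activin-only sites ranked 5. The replicate 1 libraries of both treatments alone shared 4649 sites, and activin replicate 1 with palbociclib replicate 2 alone shared 1380. A site of 1 treatment must be in both its libraries and in neither of the others, so leaving out any library eases the calls by construction. Without activin replicate 2, 1394 sites were palbociclib-only and 5057 were activin-only. The palbociclib-only count was 9465 without activin replicate 1, 3446 without palbociclib replicate 1 and 8406 without palbociclib replicate 2. The activin-only count was 849, 229 and 298 in the same order. Of the 4 libraries, only activin replicate 2 turned the direction of the full lists when left out. The ratio of palbociclib-only to activin-only sites was then 0.276, against 11.1 without activin replicate 1. With an activin library left out, activin-only sites need 1 list and palbociclib-only sites 2, which by itself favours such a turn.

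Some of the best-ranked palbociclib-only and activin-only sites lay next to each other. Over all such sites, 45 of the 1303 palbociclib-only sites and 43 of the 126 activin-only sites (34.1%) had a site of the other kind within 2000 bp. The other splits had such neighbours too: in the smaller set, 58 of 148 sites (39.2%) by replicate number and 28 of 60 (46.7%) in the crossed split. The first palbociclib-only site was on chromosome 22 from 39707086 to 39707087, with scores of 240 in replicate 1 and 143 in replicate 2. The first activin-only site was on the same chromosome from 39707752 to 39707832, 665 bp away, with scores of 142 and 35.2. The regions around 126138693 to 126139110 on chromosome 11 and 45553307 to 45553614 on chromosome 21 each held such a pair too. On chromosome 11 the palbociclib-only site ran from 126139107 to 126139110 and the activin-only site from 126138693 to 126138723, 384 bp apart. On chromosome 21 the palbociclib-only site ran from 45553307 to 45553315 and the activin-only site from 45553607 to 45553614, 292 bp apart. Other leading palbociclib-only sites were on chromosome 5 from 89705469 to 89705485 and on chromosome 6 from 42847258 to 42847299. Other leading activin-only sites were on chromosome 12 from 56510471 to 56510498, on chromosome 6 from 111197476 to 111197491 and on chromosome 16 from 30389377 to 30389381. All 10 of the best palbociclib-only sites had a summit of the other treatment within 258 to 665 bp. All 10 of the best activin-only sites had one within 292 to 1469 bp.

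**Figure D3:**
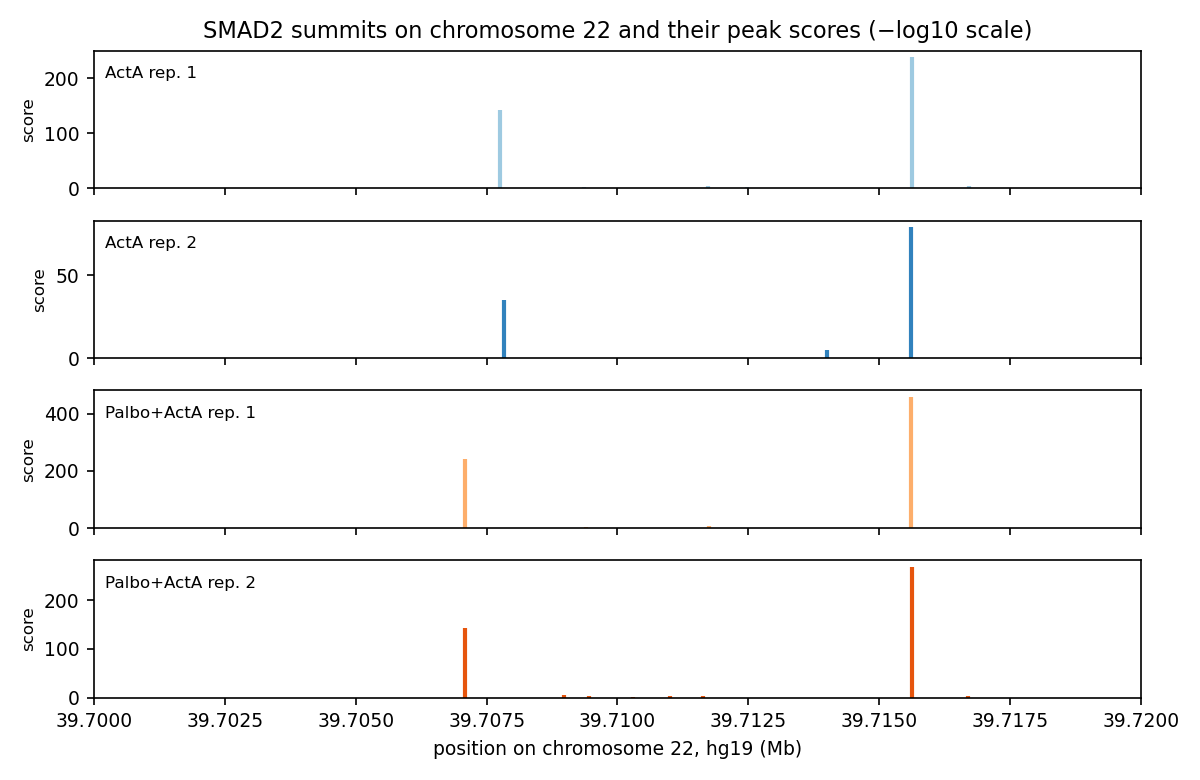
SMAD2 summits in a region of chromosome 22 (hg19; horizontal axis in Mb) in the 4 libraries, each line a summit and its height the authors' peak score (each panel has its own scale, from 0). The right-hand summits, at 39715604 to 39715634, coincide in all 4 libraries, and the left-hand ones lie at 39707086 and 39707087 in the palbociclib libraries and at 39707752 and 39707832 in the activin libraries.

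Most sites assigned to 1 treatment had a summit of the other treatment nearby. A summit of an activin library lay within 2000 bp of 961 of the 1303 palbociclib-only sites, or 73.8% (Wilson 95% interval 71.3 to 76.1). A summit of a palbociclib library lay within 2000 bp of 118 of the 126 activin-only sites, or 93.7% (88.0 to 96.7). Counted as absent only where no such summit lay within that distance, 342 palbociclib-only and 8 activin-only sites were left. At the 5812 sites with 1 summit per library, the contrast of summit positions by treatment lay between those of the other splits of the libraries. It made up 32.2% of the variation of summit position between libraries, against 37.3% for the replicate number and 30.5% for the crossed split (activin replicate 1 and palbociclib replicate 2 against the other 2). Independent libraries give 33.3% each. The median shift was 17 bp by treatment, 17.5 bp by replicate number and 15.5 bp by the crossed split.

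To compare lists of the same length, each was reduced to its 7241 best-scored summits. The lowest score kept was 37.71 in activin replicate 1, 55.78 in palbociclib replicate 1 and 25.39 in palbociclib replicate 2. It was 1.4 in activin replicate 2, whose list was kept whole with its weak summits. In these lists 4899 of 9949 sites were common to all 4 libraries, or 49.2% (Wilson 95% interval 48.3 to 50.2). Palbociclib-only sites numbered 400, the highest of the 6 pair counts, and activin-only sites numbered 210, ranking 4 of 6. The other pairs shared 267 sites (both replicate 1 libraries), 225 (both replicate 2 libraries), 148 (activin replicate 1 with palbociclib replicate 2) and 89 (activin replicate 2 with palbociclib replicate 1). Both treatment pairs together held 610 sites, against 492 for the pairs of equal replicate number and 237 for the crossed pairs. The best-scored sites of 1 treatment that were nowhere in the full lists of the other numbered 48 for palbociclib and 73 for activin alone, so the direction turned under this stricter reading. With the best 50% of these summits, the counts were 344 palbociclib-only and 297 activin-only, the highest of the 6 pairs, and the next was 125. The treatment pairs then held 641 sites, against 234 for the pairs of equal replicate number and 95 for the crossed pairs. With a library left out fewer lists decide, and both counts were higher. Without activin replicate 2 there were 1385 palbociclib-only and 2556 activin-only sites, and without activin replicate 1 there were 1271 and 1403. Without palbociclib replicate 1 the counts were 727 and 443, and without palbociclib replicate 2 they were 718 and 415.

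**Figure D4:**
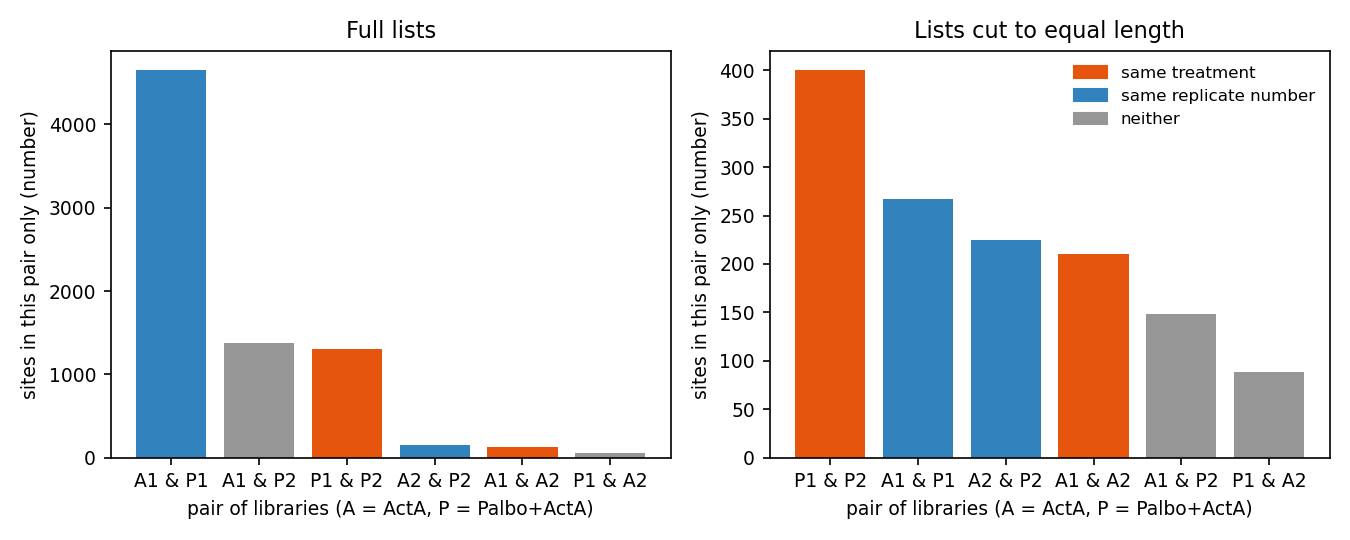
Number of SMAD2 sites found in both libraries of a pair and in neither of the others (vertical axes, from 0), for the full lists and for lists of 7241 summits each; A stands for activin and P for palbociclib with activin, followed by the replicate. The treatment pairs hold 1303 and 126 sites in the full lists, and 400 and 210 in the lists of equal length.

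Ranks over the 5829 common sites were then compared site by site, a comparison chosen after the data were seen. The site ranks were expressed as percentiles, with 0 for the strongest site and 100 for the weakest. The contrast between treatments made up 58.5% of the variation between libraries, the contrast between replicate numbers 25.9% and the crossed contrast 15.7%. Libraries with independent errors give 33.3% each. At 1528 sites both palbociclib libraries ranked above both activin libraries, and at 1643 sites both ranked below. Together these were 54.4% of the sites, against 28.4% for the replicate numbers and 17.1% for the crossed split. With no effect and the noise of each treatment taken from its replicates, simulation gave 34.2%, 32.8% and 33.0%. It used 1 SD per treatment. With more unequal noise, independent errors could give up to 50%, which is much nearer the observed 54.4%. The simulated errors were independent between libraries, so these values do not cover errors that libraries share. The change from activin to palbociclib in replicate 1 correlated with the change in replicate 2 (Pearson's r = 0.595 across sites). With the palbociclib libraries exchanged between the pairs, r was 0.392. The changes within a pairing share no ChIP library. The largest gain was at a site on chromosome 3 from 49142146 to 49142244. Its percentile was 91.2 ± 12.1 in the activin group and 26.5 ± 1.96 in the palbociclib group (SD, n = 2 each). A site on chromosome 13 from 45563580 to 45563711 moved from 93.0 ± 2.5 to 30.4 ± 7.53. The largest loss was on chromosome 19 from 39421642 to 39421663, from 18.5 ± 1.18 to 82.8 ± 0.655. A site on chromosome 21 from 40721611 to 40721642 moved from 21.0 ± 9.96 to 81.4 ± 6.1. These sites are extremes picked after their values were seen. Both libraries of a treatment were called against the same input library, so the contrast between treatments is also one between inputs.

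Summits were spread over the chromosomes in nearly the same way in both treatments. Chromosome 1 held the largest share, 10.9% ± 1.33 in the activin group and 10.3% ± 0.0173 in the palbociclib group (SD, n = 2 each). Chromosome 19 followed with 7.34% ± 1.22 and 7.83% ± 0.767, and chromosome 17 with 6.39% ± 0.444 and 6.72% ± 0.149. The X chromosome held 2.97% ± 0.0369 and 3.09% ± 0.155. Between the group means, 2.19% of the summits would have to change chromosome to make the distributions equal. Between the replicates of a group the value was 4.94% for activin and 2.43% for palbociclib. Those are distances between single libraries, and averaging 2 libraries lowers the distance between group means, so the measures are unlike. In lists of equal length the groups differed by 1.09%, the activin replicates by 2.13% and the palbociclib replicates by 1.01%. The treatments did not overlap on 4 of 23 chromosomes, where libraries of equal spread give 33.3% by chance. These were chromosomes 10, 16 and 21, higher after palbociclib, and chromosome 14, lower after palbociclib. Chromosome 16 moved from 4.90% ± 0.0285 to 5.17% ± 0.0644, a change of 0.273 percentage points.

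**Figure D5:**
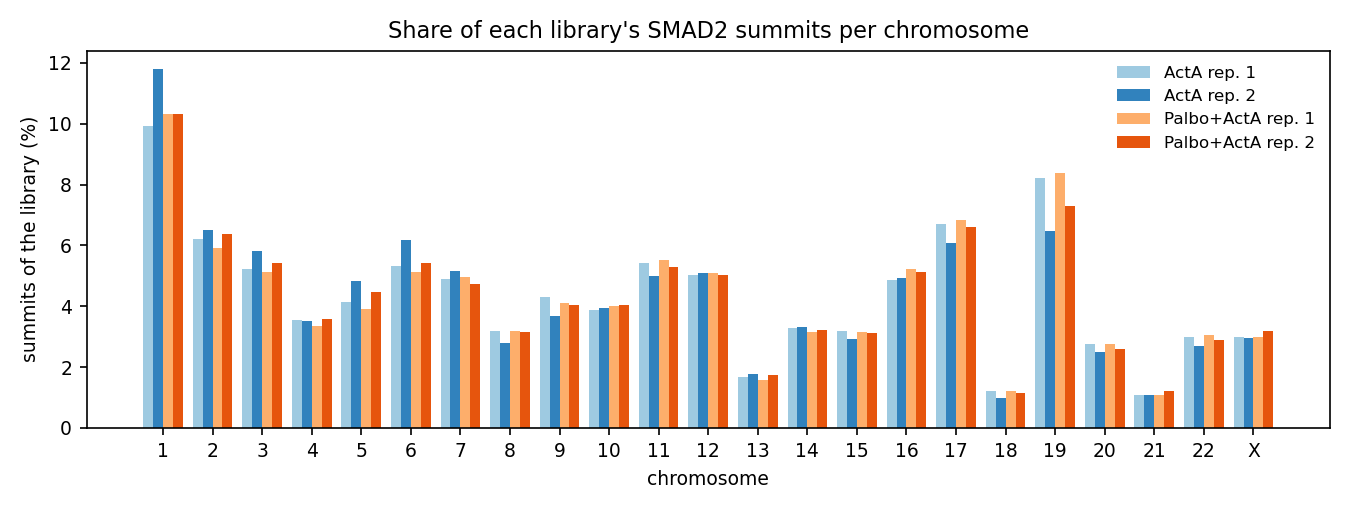
Share of each library's SMAD2 summits on chromosomes 1 to 22 and X (vertical axis in percent of the library's summits, from 0); each bar is 1 library. Chromosome 1 holds 9.92% to 11.8% and chromosome 19 holds 6.48% to 8.38% of the summits of a library.

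Common sites were densest in a few windows of 5 Mb. The first 5 Mb of chromosome 16 held 66 of the 5829 sites common to all libraries. The window from 30 to 35 Mb of chromosome 6 held 65. Windows of chromosome 19 from 10 to 15 Mb and from 45 to 50 Mb held 56 and 52. The share of summits in the chromosome 16 window was 1.47% ± 0.103 in the activin group and 1.44% ± 0.0611 in the palbociclib group (SD, n = 2 each). In the chromosome 6 window it was 1.05% ± 0.234 and 0.853% ± 0.0511. Both differences were smaller than the larger spread between replicates. Over 252 windows, the log2 ratio of summit shares in replicate 1 was set against that in replicate 2, with r = 0.025 (permutation p = 0.69, 0.69 after Benjamini-Hochberg adjustment) and rho = 0.019 (permutation p = 0.76, adjusted 0.94). Without the 2 windows farthest from the median r was 0.02. With 10 Mb windows r was 0.133 (permutation p = 0.038, adjusted 0.11) and rho 0.107 (permutation p = 0.094, adjusted 0.28), and without the 2 farthest windows r was 0.095. With 2 Mb windows r was 0.04 (permutation p = 0.57, adjusted 0.69). These 3 relations were chosen after the data were seen, and none passed the adjustment.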

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

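Alternatives fixed before the data were examined and a few added later (score of at least 20, the rank and window results, and equal lengths for overlap or with a library left out) gave these values. For the summit number, 8 of 9 alternatives kept the direction and all p-values stayed above the threshold, which the design cannot pass. With a score of at least 20 the log2 ratio was 1.71, with 888 such summits in activin replicate 2 and 8374 to 12119 in the others. The exception was -0.16 without activin replicate 2, and the values without 1 library ran from -0.16 to 1.66. With the replicate number as a block, the mean log2 ratio was 0.75 ± 0.93 (SD of 2 pairs; exact sign-flip p = 0.5, the smallest possible). The labels do not say whether a number marks a shared batch. Rank deviations of the replicates in the 2 groups correlated at 0.264 over 5829 sites, where independent errors give no correlation on average. Libraries of equal replicate number thus shared some deviation in ranks, but 2 pairs cannot show a pairing. The sites in all 4 libraries numbered 5887 to 14053 without 1 library. Palbociclib-only sites numbered 563 when joined within 1000 bp, 400 in equal-length lists, 342 with absence over 2000 bp, and 1394 to 9465 without 1 library. Activin-only sites numbered 71 when joined within 500 bp, 22 within 1000 bp, 68 with a score of at least 5, 210 in equal-length lists, 8 with absence over 2000 bp, and 229 to 5057 without 1 library. With equal lengths and without activin replicate 2 the counts were 1385 and 2556. Leaving out a library leaves fewer lists to decide, so these counts rise by construction. The ratio of palbociclib-only to activin-only sites was 11.1 without activin replicate 1 and 0.276 without activin replicate 2. In equal-length lists, sites absent from the other group's full lists numbered 48 (palbociclib) and 73 (activin); without 1 library the counts ran from 718 to 1385 and from 415 to 2556. The correlation between windows was 0.133 with 10 Mb windows, and the cause was not tested. Overlap between pairs, rank correlation and chromosome distribution moved by less than the replicate spread under each alternative run. With equal lengths, though, the overlap difference went from -3.7 to 2.46 percentage points and the chromosome difference from 2.19% to 1.09%. The treatment share of rank variation was 57.6% to 60.1% under its alternatives. The promoter, gene list and motif alternatives were not run. Unknown depth limits every count of absent sites.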

Other observations

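The observations and tests in this part were chosen after the data were seen, apart from the criteria of 3 tests: neighbouring sites, close summits and the other sites of chromosome 1. The 50 sites with the best mean rank in all 4 libraries gathered into groups. There were 14 that lay within 100 kb of another of the 50, against a mean of 0.561 and a highest value of 6 in 1000 random draws of 50 common sites. They formed 6 groups. A group of 3 sites spanned 143 kb of chromosome 1 from 28832476 to 28975371, and another group of 3 spanned 47.9 kb of chromosome 17 from 56709168 to 56757033. A pair on chromosome 15 from 65588410 to 65597363 spanned 8.95 kb and had mean ranks of 4.875 and 10.25. The other pairs lay on chromosome 1 from 45187391 to 45285620 and from 147735947 to 147806738, and on chromosome 6 from 26032197 to 26104312. Chromosome 1 held 19 of the best 50 sites, or 38.0% (Wilson 95% interval 25.9 to 51.8), and 11.5% of the other 5779 common sites. The single libraries had 14 to 20 of their best 50 sites there. Over all common sites, the best median percentiles were those of chromosome 21 at 35.9 and chromosome 1 at 37.7. The weakest were those of chromosome 19 at 62.8 and the X chromosome at 66.0, and chromosomes 19 and 21 held none of the best 50 sites. Chromosome 21 held only 55 common sites in all.

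Summits followed the number of genes along the chromosomes. Across 23 chromosomes, the number of common sites correlated with the number of protein-coding genes (r = 0.957, rho = 0.943). The 4 libraries gave rho of 0.964, 0.952, 0.942 and 0.964 for activin replicates 1 and 2 and palbociclib replicates 1 and 2. Each of these 5 relations had a permutation p of 1e-05 (1e-05 after Benjamini-Hochberg adjustment), the smallest the permutations can give. Without the 2 chromosomes farthest from the median, r for the common sites was 0.918. Chromosome 6 had the most common sites per 100 protein-coding genes, 34.3, and the X chromosome the fewest, 20.3. Chromosome 19 had 25.9. Some summits came in long runs. Chromosome 1 from 1243631 to 1254564 held 32 summits of the 4 libraries in 10.9 kb, the longest run with gaps of at most 1000 bp. It held 12 and 2 summits in the activin replicates and 8 and 10 in the palbociclib replicates.

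The first pattern weighed is the excess of palbociclib-only over activin-only sites, 10.3 to 1 in the full lists, 11.1 without activin replicate 1 and turned to 0.276 without activin replicate 2, the short list. In lists of equal length the ratio was 1.9, so unequal list lengths are a candidate explanation for most of the excess. It was 0.906 there without activin replicate 1 and 0.542 without activin replicate 2. In either case, and in the full lists too, activin-only sites then need 1 list and palbociclib-only sites 2, which favours a lower ratio. The reverse holds without palbociclib replicate 1 (727 against 443 sites at equal length) or 2 (718 against 415). For summits placed elsewhere in the same region, the ratio was 42.8 when absence required no summit within 2000 bp, with only 8 activin-only sites left. This cannot decide the question, because activin-only sites had to be clear of the longer palbociclib lists, and longer lists remove more sites whatever the placement. For palbociclib treatment as the cause of the rest, that ratio of 1.9 stood against 1.66 between the crossed pairs and 1.19 between the pairs of equal replicate number; with lists 50% as long the ratios were 1.16, 1.21 and 1.15, and against the full lists the direction turned (48 against 73 sites). Sites of the treatment pairs together outnumbered those of the other splits (610 against 492 and 237, and 641 against 234 and 95 with lists 50% as long), but for the excess of 1 treatment over the other, treatment cannot be told apart from differences between single libraries.

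The second pattern is that ranks of the common sites parted by treatment. The short list of activin replicate 2 as the whole cause is argued against only for errors that are independent between libraries. A deviation of 1 library alone then adds equally to all 3 splits, 33.3% each, and treatment made up 58.5% (57.5 to 59.6 over resampled chromosomes). Errors that libraries share could favour 1 split without an effect of treatment. Independent errors would also make the other 2 contrasts equal on average, but they were 25.9% by replicate number and 15.7% crossed. Independence therefore did not hold in full, and 33.3% is only a reference. The interval covers the spread over sites, not that between libraries. Summit placement is argued against by the 3145 sites whose summits lay within 50 bp of each other in all 4 libraries, where treatment still made up 62.5% of the variation. The treatment contrast of common sites within 1000 bp of each other, which would share input background, correlated at -0.071 (53 pairs, bootstrap 95% interval -0.299 to 0.168), too wide to exclude an effect of the input. Each treatment has its own input, so input and palbociclib cannot be told apart, and a change of SMAD2 occupancy with palbociclib may be put only as a hypothesis.

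The third pattern is the gathering of the strongest sites on chromosome 1. A random draw is argued against, since none of 10000 random draws of 50 sites had over 16 there (permutation p = 0.0001, the smallest they can give). Several sites counted in 1 region are argued against too, since sites joined within 100 kb made 42 regions with 35.7% of them on chromosome 1 (Wilson 95% interval 22.99 to 50.83), against 11.1% of the regions of the other common sites. Extra copies of chromosome 1 in this line are a candidate explanation, since its other common sites also ranked better by 12.7 percentile points in the median. Their medians were 39.0 before and 39.5 after the widest gap of the chromosome. Chromosome 1 held 15.1% of the common sites ranked 51 to 500 and 17.1% of those ranked 501 to 1500. Further down it held 11.2% at ranks 1501 to 3000 and 9.16% at ranks 3001 to 5829. The step to 38.0% in the best 50 is not accounted for by the shift of the median. Copy number was not analysed here, and the input DNA of the same line carries the same copies. Over all common sites chromosome 21 had a better median than chromosome 1 (35.9 against 37.7). It held none of the best 50, but with only 55 of the 5829 common sites that absence says little. Signal that any antibody would give at these sites stays open without a control antibody library, and no biological explanation was tested, because the groups of the design do not bear on it.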
